A study of Nothobranchius furzeri with 15 samples.

How the data were processed

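RNA from brain, liver and skin of the annual killifish Nothobranchius furzeri was measured by RNA sequencing in 15 samples, 5 per tissue. The fish belonged to the short-lived laboratory strain GRZ and were 12 weeks old, per the labels. Total RNA was made into libraries with an Illumina TruSeq kit, per the labels' protocols. The submitters' processing notes name CASAVA 1.8.2, Bowtie, TopHat2 2.0.6 and featureCounts 1.4.3-p1, without saying which step each served. The genome build and the annotation are not given in the sources used here. Neither is the strandedness of the counting nor the treatment of reads that match several genes, so near-identical copies and overlapping genes are uncertain.

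The authors deposited read counts in 2 tables, and both were treated as raw counts because their values are whole numbers with a different total in each sample. One table counts reads per entry of a killifish transcript catalogue, and the other per gene model of the killifish genome. Each catalogue entry carries a gene identifier, of zebrafish in all entries but 1, and a flag for a best bidirectional hit. The authors deposited the flag with the counts, and it is explained per the file headers. An entry of the catalogue is called a gene here, although several entries can belong to 1 gene. The catalogue holds 18311 entries, of which 196 had no count in any sample. Of these entries 13561 are best bidirectional hits and 4750 are not. They carry 15476 different identifiers, 2313 of which are shared by several entries. The genome table holds 23546 gene models. The authors also deposited RPKM values for both tables, that is, reads per kilobase of gene and per-million counted reads, per the file headers. The deposited RPKM sheet of the catalogue has 60 more columns, for samples outside the 15 analysed, and these were not used.

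The files do not pair either kind of killifish identifier with gene names. None of the catalogue, zebrafish or genome identifiers matched the 38438 genes of the reference table of assembly NfurGRZ-RIMD1 (0 matches for each kind). By a rule fixed before the data were examined, the catalogue was then the main table and the genome table an alternative. The 29 gene lists fixed in advance for cell types and pathways could not be matched, so no list was tested. The rule for named genes took, per comparison and direction, the largest log2 fold changes among genes with a symbol, an adjusted p under 0.05, a mean of at least 100 CPM (counts-per-million) in the higher tissue and all 5 samples of the higher tissue above all 5 of the lower. With no symbols, the same rule without that condition was used, and 2 genes per direction are given by their identifiers.

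Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its count minimum of 10, which left 16611 catalogue genes, and libraries were scaled by TMM. All 15 samples entered 1 quasi-likelihood fit with a term per tissue, so the 3 comparisons share their estimate of the spread. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Fold changes are edgeR's, and the standard error (SE) given with each is its size divided by the square root of the F statistic. A gene was counted as highest in a tissue when it passed the test against each of the other tissues with at least 4-fold higher level in both. Single measures per library were compared by 2-sided exact permutation tests over all 252 arrangements, in a family of 15 tests, and in another family of 15 for the genome table. Series information describes the 5 samples of a tissue as biological replicates, so p-values measure the spread between separate samples. Intervals and floors cover counting error only, and a floor stands for 3 counts in a library. All CPM values, floors included, are scaled by TMM. For named genes whose mean in the lower tissue lies under the floor of a library there, a ratio of pooled counts is given with its 95% counting interval, since the fitted fold change depends on the prior count.

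The procedure was tested on simulated counts of 16395 genes. In each comparison with known changes, 65 genes were changed 1.5-fold, 66 genes 2-fold and 66 genes 4-fold. For brain over liver it recovered 92.4% of genes changed 4-fold, 33.3% of those changed 2-fold and 3.08% of those changed 1.5-fold, with 4 false calls. For liver over skin it recovered 90.9%, 36.4% and 0% at those sizes, with 2 false calls. Apart from the changed genes, the simulated tissues shared a common profile. Recovery and false calls between tissues that need strongly different scaling were therefore not tested. Total counts per sample ran from 17.7 to 30.8 M in the catalogue and from 20.9 to 32.8 M in the genome table. Gene lengths were computed from the deposited values, as the median over samples of the length that count, column total and RPKM imply. With these lengths, 100% of RPKM values above 0 were reproduced, within a relative tolerance of 1e-06. This shows only that a gene's implied length is the same in all samples, and is no independent check of the lengths.

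Alternatives covered DESeq2 size factors within edgeR, no scaling beyond the library total, DESeq2 1.42.0, no low-count filter, a mean of at least 5 CPM, fits of the compared tissues alone, the number in the sample titles as a block, each sample left out in turn, the genome table, and limma 3.58.1 on log2(RPKM + 1) or log2(RPKM + 0.1). The RPKM filter was a mean of at least 1 in some tissue, and it was also dropped. Python 3.11.15 with scipy 1.17.1 was used for permutation tests.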

Results

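The data set describes gene expression in 3 organs of the killifish Nothobranchius furzeri, strain GRZ, at 12 weeks of age. Brain, liver and skin were each represented by 5 samples. Brain and liver samples carry the numbers 10, 11, 13, 14 and 15, and skin samples the numbers 5, 6, 7, 13 and 14. These numbers come from the sample titles, where the same number recurs across tissues. They may mark single fish, which no label states, and the main p-values do not use them. Total counts averaged 22.9 M ± 4.61 (SD, n = 5) in brain, 23.8 M ± 2.10 in liver and 20.8 M ± 1.88 in skin. Differences in these totals between tissues did not pass the exact permutation test, with adjusted p = 0.746 for brain and liver, 0.536 for brain and skin and 0.0641 for liver and skin. At 17.7 to 30.8 M counts, a count of 0 allowed a TMM-scaled level of up to 0.0593 to 0.0895 CPM in a single brain library, 0.120 to 0.163 CPM in skin and 0.178 to 0.267 CPM in liver.

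In catalogue counts, the tissues differed in how many genes reached 10 counts and in how evenly the counts were spread. The same count stands for a higher TMM-scaled level in liver than in skin or brain. The mean TMM factor was 0.598 in liver, 1.01 in skin and 1.68 in brain. The number of genes that reach 10 counts is therefore not a measure of how many genes a tissue uses. At least 10 counts were found for 16200 ± 131 genes in brain, 13999 ± 259 in liver and 15373 ± 275 in skin (SD, n = 5). The number of genes that together held 50% of the counts was 1299 ± 138 in brain, 331 ± 82.0 in skin and 120 ± 34.0 in liver. The 100 most abundant genes took 14.7% ± 1.97 of the counts in brain, 32.3% ± 3.30 in skin and 47.8% ± 3.51 in liver. For each of these catalogue measures, every pair of tissues differed by exact permutation test (p = 0.00794, the smallest that 252 arrangements allow, adjusted p = 0.00992). In the genome table, brain again differed from both other tissues, while the liver and skin difference in evenness did not pass the test. There 102 ± 23.9 genes held 50% of the counts in liver and 129 ± 31.9 in skin (SD, n = 5; exact permutation test, p = 0.135, adjusted p = 0.202). The 100 most abundant genes took 50.1% ± 3.38 in liver and 46.8% ± 3.48 in skin (exact permutation test, p = 0.159, adjusted p = 0.211). The most abundant gene of each library held 0.703% ± 0.223 of the catalogue counts in brain, 3.87% ± 0.649 in liver and 2.50% ± 0.773 in skin. In the genome table its share was 3.88% ± 0.751 in liver and 4.64% ± 1.10 in skin, so the order of these tissues depended on the table.

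**Figure D1:**
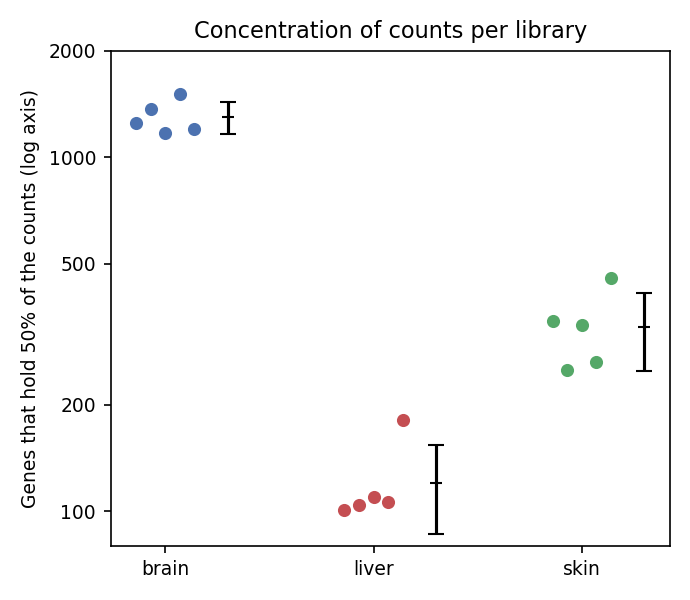
Number of genes that together hold 50% of the counts in each library, on a log axis, for brain, liver and skin in the catalogue counts. Coloured points are the 5 libraries of a tissue, and the black mark is the mean with its SD. Brain libraries sit between 1169 and 1506, skin libraries between 251 and 457, and liver libraries between 101 and 181. In the genome table, which is not drawn, skin (93 to 170) and liver (89 to 144) overlap.

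Samples of a tissue resembled each other more than samples of other tissues. The mean Pearson correlation of log2 CPM across genes, which are not independent replicates, was 0.981 between brain samples, 0.957 between liver samples and 0.959 between skin samples. Between tissues it was 0.672 for liver and skin, 0.498 for brain and liver and 0.490 for brain and skin. The biological coefficient of variation, a measure of the spread between samples beyond counting error, was 0.211 in brain, 0.409 in liver and 0.373 in skin. Without skin 7 it was 0.246 in skin, and without liver 15 it was 0.337 in liver. Skin 7 held 327 genes at 4 or more times the mean of the other skin samples, against at most 8 in any other skin sample. Those genes held 4.55% of the counts of skin 7 and at most 0.377% in the other skin samples.

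**Figure D2:**
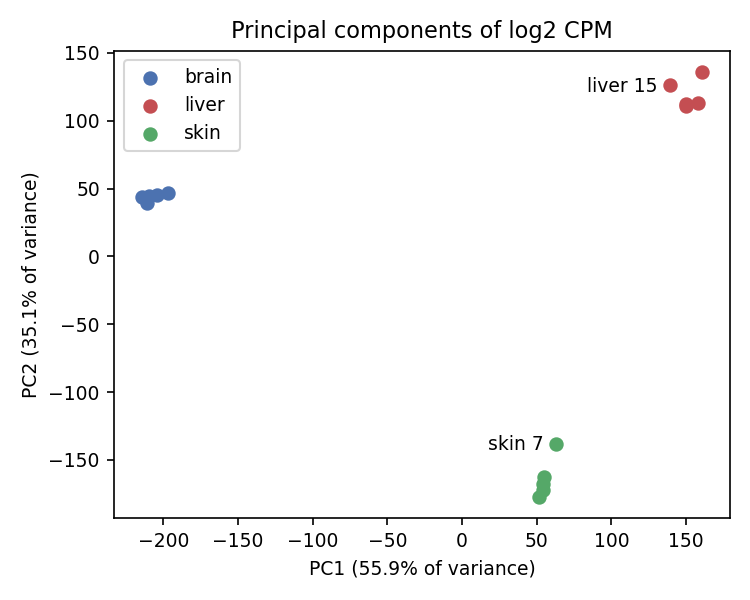
Principal components of log2 CPM, with 1 point per library coloured by tissue. The first component (55.9% of the variance) and the second (35.1%) place the 5 libraries of each tissue together, and skin 7 and liver 15 are named.

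Brain and liver were compared to find genes whose expression differs between these organs. Genes higher in brain numbered 6284 and genes higher in liver 5981, so that 12265 of 16611 tested genes (73.8%) differed by edgeR's quasi-likelihood test at an adjusted p under 0.05. Large differences were more often in favour of brain, with 3482 genes at least 4-fold higher in brain and 2385 at least 4-fold higher in liver. One of the 2 genes named for brain was Nofu_gene_3_0002905, paired with zebrafish gene ENSDARG00000027963. It reached 115 ± 31.7 CPM in brain (SD, n = 5) and 0.0270 ± 0.0370 CPM in liver, where all 5 libraries together held 2 counts. Counts pooled over the 5 libraries of each tissue and divided by their pooled scaled totals gave a ratio of 4214, with a 95% counting interval of 1167 to 34796. The fitted log2 fold change was 11.75 (SE 0.53, edgeR adjusted p = 1.23e-11) and depends on the prior count at so few reads. Nofu_gene_3_0007681 (ENSDARG00000004150) stood at 127 ± 17.6 CPM in brain and 0.125 ± 0.129 in liver, a log2 fold change of 10.05 (SE 0.55, edgeR adjusted p = 9.75e-11), or 10.78 without liver 13. Its 8 counts in liver gave a pooled ratio of 1144, with a counting interval of 581 to 2651.

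In the opposite direction, Nofu_gene_3_0017689 (ENSDARG00000043360) was measured at 23764 ± 19072 CPM in liver and 9.12 ± 2.87 CPM in brain. Its log2 fold change for brain over liver was -11.35 (SE 0.85, edgeR adjusted p = 4.05e-09) and -10.74 without liver 10. Nofu_gene_3_0008718 (ENSDARG00000035350) stood at 1249 ± 1149 CPM in liver and 0.409 ± 0.285 CPM in brain, a log2 fold change of -11.53 (SE 1.21, edgeR adjusted p = 2.61e-07). Its level in liver ran from 14.6 CPM in liver 13 to 2525 CPM in liver 15. The balance between the directions depended on the scaling. With TMM, 51.2% of the genes called were higher in brain and the median log2 fold change of all genes was 0.013, while without scaling 84.2% were higher in brain around a median of 1.49. On deposited RPKM values tested with limma the share was 85.0%, around a median of 1.11.

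Brain and skin differed in 11617 genes (69.9%), of which 5758 were higher in brain and 5859 in skin by the same edgeR test. With TMM, at least 4-fold higher levels were found for 2599 genes in brain and 2740 in skin, so that 48.7% of these large differences were in favour of brain. That share was 65.9% without scaling and 69.4% on RPKM values. The genes named for brain had nearly equal fold changes. Nofu_gene_3_0001491 (ENSDARG00000078529) stood at 181 ± 35.2 CPM in brain and 0.148 ± 0.136 in skin (SD, n = 5; log2 fold change 10.18, SE 0.44, edgeR adjusted p = 1.14e-11). Nofu_gene_3_0005849 (ENSDARG00000006640) stood at 125 ± 46.3 CPM in brain and 0.101 ± 0.170 in skin, with a log2 fold change of 10.15 (SE 0.61, edgeR adjusted p = 3.61e-10). In skin these genes had 16 and 11 counts over the 5 libraries, which gave pooled ratios of 1217 (counting interval 749 to 2129) and 1250 (699 to 2505). Both moved with skin 7, without which the log2 fold changes were 10.79 for Nofu_gene_3_0001491 and 12.05 for Nofu_gene_3_0005849.

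Of genes higher in skin than in brain, Nofu_gene_3_0003156 (ENSDARG00000058570) reached 112 ± 27.3 CPM in skin and 0.0288 ± 0.0286 CPM in brain, a fitted log2 fold change of -11.80 for brain over skin (SE 0.54, edgeR adjusted p = 2.08e-11). Brain held 5 counts of Nofu_gene_3_0003156 in all and at most 2 in a library, under the floor, so the fitted value depends on the prior count. The pooled ratio of skin to brain was 4288, with a counting interval of 1838 to 13207. Nofu_gene_3_0013973 (ENSDARG00000024433) was more abundant, at 5259 ± 2536 CPM in skin and 2.07 ± 0.931 CPM in brain (log2 fold change -11.31, SE 0.84, edgeR adjusted p = 3.94e-09). The share of called genes that were higher in brain was 49.6% with TMM, 70.4% without scaling and 71.5% on RPKM values. The median log2 fold change of all genes was 0.027, 0.759 and 0.635 in these fits.

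Liver and skin differed in 10434 genes (62.8%), with 4864 higher in liver and 5570 higher in skin by edgeR. With TMM, 1288 genes were at least 4-fold higher in liver and 2797 at least 4-fold higher in skin, so that 31.5% of these large differences were in favour of liver. That share was 17.7% without scaling and 24.5% on RPKM values. The 2 genes named for liver were the same as against brain. Of these, Nofu_gene_3_0008718 varied widely between livers, from 14.6 CPM in liver 13 to 2525 CPM in liver 15. Nofu_gene_3_0008718 stood at 0.195 ± 0.0966 CPM in skin (SD, n = 5), a log2 fold change of 12.58 (SE 1.29, edgeR adjusted p = 3.16e-07). Nofu_gene_3_0017689 stood at 7.61 ± 4.63 CPM in skin, a log2 fold change of 11.61 (SE 0.86, edgeR adjusted p = 7.31e-09) that was 10.99 without liver 10.

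Of genes higher in skin than in liver, Nofu_gene_3_0014906 (ENSDARG00000056617) stood at 249 ± 125 CPM in skin and 0.422 ± 0.574 CPM in liver. Its log2 fold change for liver over skin was -9.32 (SE 0.70, edgeR adjusted p = 7.92e-09) and -10.49 without liver 13. Nofu_gene_3_0010449 (ENSDARG00000020237) showed 383 ± 178 CPM in skin and 0.632 ± 0.5002 CPM in liver (log2 fold change -9.28, SE 0.55, edgeR adjusted p = 5.38e-10). Of all genes called, 46.6% were higher in liver with TMM, 17.2% without scaling and 16.9% on RPKM values. The corresponding median log2 fold changes of all genes were -0.031, -0.776 and -0.463. Without scaling, the 12 log2 fold changes of named genes in the 3 comparisons moved by 0.65 to 1.55 and kept their direction. Shifts of that size could not have reversed folds chosen as the largest.

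**Figure D3:**
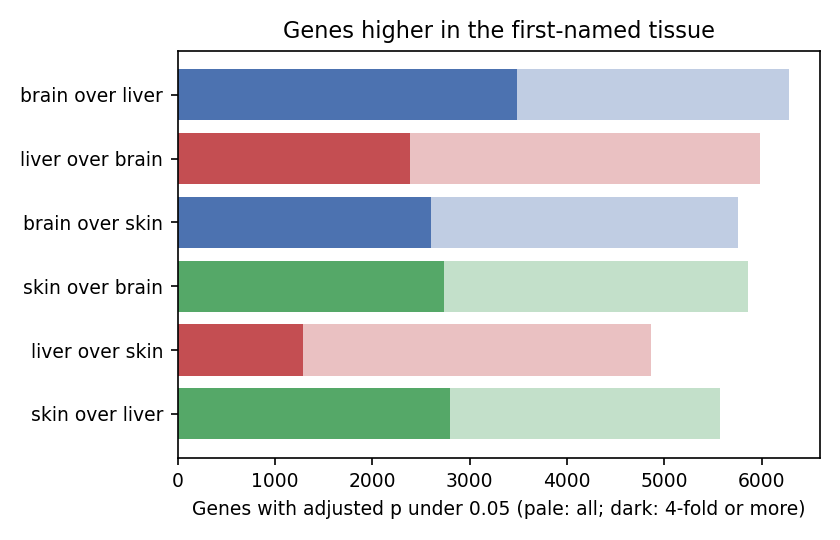
Number of genes higher in the first-named tissue for each pair and direction. Pale bars show all genes with an edgeR adjusted p under 0.05, and dark bars those at least 4-fold higher, from 1288 for liver over skin to 3482 for brain over liver.

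Across the 3 comparisons, 5819 genes (35.03%) passed the test in each, 7783 in a pair of them, 1293 in a single one and 1716 (10.3%) in none. Genes at least 4-fold higher in 1 tissue than in both others numbered 2222 for brain (13.4% of genes tested), 1403 for skin (8.45%) and 913 for liver (5.50%). The same count stands for a lower TMM-scaled level in brain than in liver, so genes can pass the filter at lower levels in brain. These set sizes, and the 4-fold numbers of each comparison, therefore do not measure how many genes each tissue favours. Independent lists of the same sizes would share 545, 461 and 185 genes. Both comparisons of a tissue use the same libraries, and 10 simulations of unchanged groups gave 0 such genes for each tissue. When separate libraries of the tissue were used for each comparison, the median overlap over 10 splits was 2207.5 genes for brain, 1356.5 for skin and 849.5 for liver. Because the simulation leaves out real effects and the independent lists leave out the shared libraries, neither gap measures a shared effect.

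The 913 liver genes had the highest levels, with a median of 158 CPM in liver, against 31.7 CPM for the brain genes in brain and 39.3 CPM for the skin genes in skin. They took 53.1% ± 3.95 of all counts in liver (SD, n = 5), 2.40% ± 0.314 in brain and 1.8001% ± 0.413 in skin. The skin genes took 36.4% ± 3.52 of the counts in skin, 1.52% ± 0.0948 in brain and 0.747% ± 0.108 in liver. The brain genes took 24.4% ± 1.503 of the counts in brain, 0.906% ± 0.0950 in skin and 0.370% ± 0.0786 in liver. Each set was chosen on these libraries, so its share is a description and not an independent test. The median fold over the nearest other tissue was 14.6 for brain genes, 10.98 for liver genes and 11.03 for skin genes. Genes with no count in any library of the other tissues numbered 11 for brain, 4 for skin and 0 for liver. A count of 0 allows a higher level in liver than in brain, so these numbers do not compare the tissues evenly. Genes at least 4-fold lower in 1 tissue than in both others numbered 1285 for liver, 1174 for brain and 274 for skin. Leaving out skin 7 and liver 14 together gave 2251 genes highest in brain, 1021 in liver and 1438 in skin. In the absence of scaling, 3259 genes were highest in brain, 1349 in skin and 553 in liver.

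**Figure D4:**
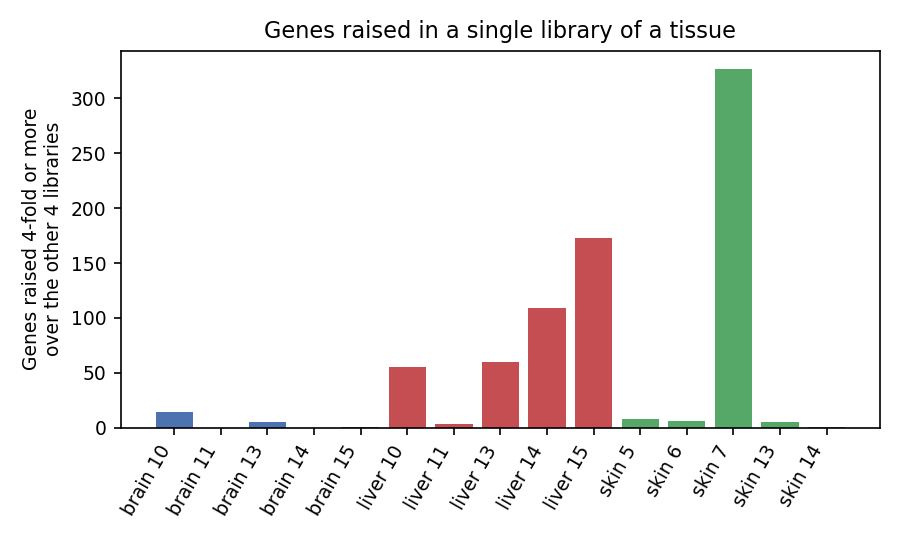
Number of genes in each library with at least 10 CPM and at least 4 times the mean of the other 4 libraries of its tissue. Skin 7 has 327 such genes, liver 15 has 173 and liver 14 has 109, and no other library has more than 60.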

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

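Tests of the origin of the genes raised in skin 7, and of sequencing depth in liver 15, were chosen after those patterns had been seen. Of 34 groups of 5 samples examined by Dixon's outlier rule (critical value 0.71), 4 held a sample far from the rest. For independent groups chance gives about 1 in 20, or 1.7. The groups were not independent, since the genes for 50% of the counts and the share of the 100 most abundant both flagged liver 15. No conclusion is drawn from 4 against 1.7.

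Skin 7 held 327 genes raised at least 4-fold over the other skin samples, and the next skin sample held 8. With an 8-fold minimum, chosen after seeing the data, 208 remained. Liver RNA is argued against, since the 100 most abundant genes highest in liver had a median excess in skin 7 of 0.00253% of their liver level, far below what an admixture of whole liver RNA needs. Other values go the opposite way. Of the 327 genes, 82 (25.1%, against 5.50% of all genes tested) are highest in liver. Skin 7 correlated with liver at 0.704, where the other skin samples averaged 0.663. The 82 genes had a median excess in skin 7 of 17.4% of their liver level. They were picked for being raised in skin 7, so a positive excess was fixed by that choice and goes neither way. By contrast, 200 of the 327 (61.2%) had an excess above their level in each liver sample, which an admixture of liver RNA as the whole source forbids. A source that shares some transcripts with liver stays open. For brain RNA the same test gave 0.317%, between the bounds set for it, and left the question open. A second test was then added because the first had been inconclusive: 300 of the 327 genes had an excess in skin 7 above their level in each of the 5 brain samples, which an admixture of brain RNA as the whole source forbids. Counting against the catalogue is argued against too, since the genome table gave 449 raised genes in skin 7 and at most 7 in another skin sample.

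RNA of a tissue not sampled here, present in both skin 7 and liver 14, is a candidate source that cannot be told apart from other origins. The 327 genes had a median log2 fold of 0.402 in liver 14 over the other livers (interquartile range -0.019 to 1.71), against at most -0.230 in any other liver. This lay between the bounds of 0.3 and 1 set for the test. Of the 109 genes raised in liver 14, 58 were also raised in skin 7, where 2.15 would be shared by independent lists, while liver 15 shared 1 of 173. No gene names were at hand to identify a tissue, and no biological explanation was tested, as the labels give no difference between samples of a tissue.

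Liver 15 spread its counts over more genes than the other livers. It needed 181 genes for 50% of its counts, where the next liver needed 110, and its 100 most abundant genes held 41.6% of the counts, where the next held 48.5%. A few very abundant genes are argued against as the whole source: without the 10 most abundant liver genes, liver 15 needed 292 genes and the other livers at most 219. Its 23.3 M counts lay within the range of the other livers, which argues against depth. A lower share of the main liver cell type may contribute and stays open, since genes highest in liver had a median log2 fold of -0.455 in liver 15 with 71.1% of them lower, short of the 75% required in advance. No other biological explanation was tested.

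The liver gene Nofu_gene_3_0017689 stood at 56731 CPM in liver 10, with the next liver at 21717 CPM.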

How the results depend on the processing

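Of 483 recomputed counts of genes, 441 stayed within 1.5 times the reported value, among them all 270 with 1 sample left out. The 12 named results kept their direction and their side of the threshold in all 240 recomputations, with adjusted p of at most 0.00112. Those 240 cover other scalings, DESeq2, the block and left-out samples. Fold sizes were less stable. All 12 moved by over 1.5 times with no scaling, by up to 1.55 on the log2 scale (Nofu_gene_3_0017689, brain over liver, -11.35 to -9.80), and none did with DESeq2 or its size factors. Omitting skin 7 and liver 14 together, and measuring evenness in the genome table, were chosen after seeing the data. In the genome table, liver minus skin was -27.8 genes for 50% of the counts, 3.27 percentage points for the 100 most abundant genes and -0.759 points for the most abundant gene, none of which passed the exact permutation test. Catalogue values were -210.8, 15.5 and 1.37, and the cause was not tested. The biological coefficient of variation with 1 sample left out ran from 0.337 (without liver 15) to 0.436 in liver and from 0.246 (without skin 7) to 0.391 in skin. The 42 counts that moved further came from fits with no scaling or on RPKM values, which share a per-total scaling. The 4 values in each series below are for no scaling, log2(RPKM + 1), log2(RPKM + 0.1) and log2(RPKM + 1) with no filter. Genes higher in brain than in liver numbered 11623, 11357, 11561 and 12201, and genes higher in liver than in brain 2189, 1999, 2067 and 2048. Genes at least 4-fold higher in liver than in brain numbered 1008, 682, 892 and 681. Genes higher in brain than in skin numbered 9022, 9115, 9066 and 9738, and genes higher in skin than in brain 3799, 3632, 3607 and 3862. Genes higher in liver than in skin numbered 1913, 1752, 1831 and 1822, and genes higher in skin than in liver 9219, 8610, 9131 and 9048. Genes highest in liver numbered 553, 469, 540 and 469. At least 4-fold higher in brain than in liver were 6377 genes with no scaling and 6028 on log2(RPKM + 0.1). For the 3 RPKM fits in the same order, genes at least 4-fold higher in skin than in brain numbered 1143, 1650 and 1143, and those higher in liver than in skin 611, 802 and 611. Both fits on log2(RPKM + 1) gave 890 genes highest in skin. With no scaling, 8473 of the 12265 genes called between brain and liver kept their call and direction and 1488 were called in the opposite direction.

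A few very abundant genes are a candidate cause of the unscaled imbalance. Without the 100 most abundant genes of each tissue (239 in all), the share called higher in brain with no scaling was 71.5%, against 84.2% with all genes and 50.6% with TMM on the reduced set. The gap to TMM narrowed and stayed just above the 20 points set in advance, so these genes account for part of the imbalance and not all of it.

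The replicate block gave 12184 genes between brain and liver, 9508 between brain and skin and 7991 between liver and skin. It moved 5 of the 12 named folds by over 1.5 times, the furthest being Nofu_gene_3_0008718 for liver over skin (log2 fold change 12.58 to 10.43) and Nofu_gene_3_0005849 for brain over skin (10.15 to 11.82). Deviations of brain and liver samples with the same number correlated at 0.083 to 0.185, above 0.1 in 3 of 5 pairs, and 4 of 5 brain samples matched their own number best. Same-numbered pairs with skin correlated at 0.03 and 0.261 for brain 13 and 14 and at 0.079 and 0.083 for liver 13 and 14, and liver 14 reached 0.285 with another skin number. The shared numbers may mark fish, but no label says so, so the main fit did not pair samples. Tests of the gene lists and their alternatives were not run, because no identifier matched the 1 reference assembly that was tried. Depth limits genes near the floor per library, which ran from 0.0593 CPM in a brain library to 0.267 CPM in a liver library.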

Other observations

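The tests of zebrafish pairs, best hits, length and other divisions of the samples were set before their results were seen, while the split of best hits by tissue and the ratio of the tables were chosen afterwards. Genes paired with the same zebrafish gene tended to be highest in the same tissue. Among 378 pairs of tissue-highest genes with a common zebrafish identifier, 84.4% were highest in the same tissue, against a mean of 37.5% and a highest value of 48.1% in 10000 shuffled assignments. Shared ancestry, or fragments of 1 gene listed as several entries, may account for this, and the files do not separate these from reads divided between near-identical copies. The remaining 59 pairs were highest in different tissues.

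Genes that are not best bidirectional hits were more often highest in a single tissue, at 32.4% of 3708, than best hits, at 25.9% of 12903, a difference of 6.49 percentage points (Fisher's exact test, 2-sided, p = 1.13e-14, adjusted p = 7.92e-14 over 7 such tests). The hypothesis that lineage-specific copies differ in use required a higher share in each of 3 equal classes of mean expression. The shares were 31.2% and 30.1% in the low class, 32.3% and 21.6% in the middle class and 35.1% and 26.7% in the high class. The share was higher in each class, although in the low class the difference did not pass Fisher's exact test (adjusted p = 0.407). Such shares do not compare an entry with its own copies, so they cannot show that copies differ in use. Among tissue-highest entries with a common zebrafish identifier, 84.4% of 378 pairs were highest in the same tissue and 59 pairs in different ones. The hypothesis therefore stays open. In liver the association was reversed, with 4.72% of the genes that are not best hits highest there, against 5.72% of best hits (Fisher's exact test, p = 0.0178, adjusted p = 0.0207). The higher share therefore does not extend to genes highest in liver. The shares were 17.2% and 12.3% in brain (Fisher's exact test, adjusted p = 1.28e-13) and 10.4% and 7.87% in skin (adjusted p = 1.89e-06). Fisher's exact test treats entries as independent. In the catalogue 5148 entries share a zebrafish identifier, and tissue-highest entries that share an identifier tended to be highest in the same tissue. The p-values for best hits can therefore be too small, and the shares are a description.

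By the catalogue lengths that the RPKM values imply, genes highest in brain were longer, with a median of 2764 nt. The median was 2405 nt for genes highest in skin, 2197 nt for liver and 2540 nt for no tissue. Permutation tests of the difference from liver and of that from skin each gave p = 0.0002 (2-sided), the smallest that 10000 shuffles allow, and the difference from genes highest in no tissue was not tested. Longer brain transcripts may underlie this, although the completeness of catalogue entries was not tested.

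The genome table held more counts than the catalogue, and the ratio differed by tissue. It was 1.05 ± 0.0370 in brain, 1.17 ± 0.0436 in liver and 1.34 ± 0.0315 in skin (SD, n = 5). Each pair of tissues differed by exact permutation test (p = 0.00794, the smallest possible, adjusted p = 0.00992).

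Other divisions of the samples were tried for each count, with 100 divisions each including the real one. In fits of the 2 tissues alone, the real division gave 11958 genes between brain and liver, 12211 between brain and skin and 9333 between liver and skin. The highest other divisions gave 0, 0 and 36, so 1 of 100 was as large in each, and no more than this rank is claimed. The other divisions mix tissues, which widens the spread within their groups, so their low counts measure neither false calls nor the size of the effect. For genes highest in brain (2222) and in skin (1403), the highest other division gave 0 and 1 of 100 was as large, with the same limit. For genes highest in liver (913), 2 of 100 were as large, so the condition set in advance, that other divisions give fewer genes, was not met by 1 division. It gave 2369 genes and had placed all 5 brain samples under the liver label, which was looked up only after its count was seen and points to the structure of the samples. No more than this rank is claimed for genes highest in liver.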
